A study of Mus musculus with 6 samples.

How the data were processed

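RNA was sequenced from mast cells isolated from mouse lymph nodes. Per the labels, 3 libraries came from uninvolved nodes (uLN) and 3 from nodes with tumour metastasis (mLN). Total RNA was extracted with a Qiagen RNeasy kit and made into mRNA libraries with a BGI kit for DNBSEQ sequencing, per the labels' protocols. How the mast cells were isolated, and the tumour and mouse strain, are not given in the sources used here. Per the submitters' processing notes, cutadapt, FastQC and TopHat were used with the mouse genome build GRCm38, with no versions. The tool that turned alignments into counts, and whether it used strand, are not given in the sources used here.

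The authors deposited 1 table of estimated counts per gene, with 1 column per library and no scaling stated. Between 32.2% and 32.8% of the values of a library were not whole numbers, so these are expected counts, as tools give when they share a read between genes or transcripts. They were rounded to whole numbers for the tests. The table has 17891 rows, of which 1 names no gene and was left out, which leaves 17890 genes. Of these, 17764 were found by gene ID in the RefSeq annotation of GRCm38.p6, from which coordinates were taken. The table covers 17550 of the 21900 protein-coding genes of that annotation. A spreadsheet had turned 26 gene symbols into dates, and these were restored by gene ID, while 10 symbols that had become numbers were left as they were. None of the 15 listed genes of the mitochondrial genome are in the table, so mt-Rnr2 was not analysed here. The table also holds 0 immunoglobulin or T cell receptor segments.

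Library totals ran from 17643916 to 17799420 counts and 15639 to 16218 genes had at least 1 count. A floor of 3 reads per library corresponds to 0.164 to 0.172 CPM, the read count scaled to library size. Where every uLN library had 0 reads, the fold is given as a lower bound against that floor, and where uLN held 1 to 3 reads, as a read ratio with a 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

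The comparison of mLN with uLN used edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test, TMM normalisation and the default expression filter. That filter kept 12706 genes and removed 5184. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Values are given as TMM-normalised CPM, mean ± SD over 3 libraries. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Before the data were examined, 42 gene lists with 1183 entries were fixed, of which 1099 were found in the table, 2 of them by synonym. Lists with at least 5 tested members were tested with camera in limma 3.58.1, which asks whether the members of a list move differently from the other genes. It ran with a preset correlation between genes of 0.01 and a prior count of 2. With an estimated correlation, 0 of the lists were called.

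Genes were named by a rule also fixed before the data were examined. It takes Lcn2, Kit, Fcer1a, Ms4a2, Cpa3, Mcpt4, Cma1, Tpsb2, Hdc and mt-Rnr2 in any case. It then takes the 10 called genes with the largest rise and the 10 with the largest fall, among those with a mean of at least 5 CPM whose groups did not overlap, leaving out predicted gene models, pseudogenes and receptor segments. For each list it takes up to 4 members in the order of their adjusted p. Where fewer than 2 members pass, it takes the most abundant members instead, up to 2. Of the genes this rule takes, 2 are not reported here.

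The tests were first run on simulated data for mLN against uLN, drawn for 12706 genes from the means and sizes of the real libraries, with 50 genes changed at each of 4 sizes. The edgeR test recovered 48.0% of genes changed by 1.25-fold, 86.0% at 1.5-fold, 90.0% at 2-fold and 100% at 4-fold, and 13 of its 175 calls were false. When the 37 tested genes of the hypoxia list were moved by 1.5-fold, camera called that list and no other of 36. The simulated genes were drawn independently and the other genes left unchanged, so this run does not test camera on genes that move together. In the real data the hypoxia list had an estimated correlation of 0.303, and 67.4% of tested genes were called.

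Each pair of libraries was compared by a chi-square test of its counts over genes with at least 20 reads in the pair. The median per gene was 0.69 to 0.75 among the uLN pairs and 0.73 between mLN replicates 1 and 2, where counting error alone gives 0.45. It was 2.43 and 2.45 for mLN replicate 3 against mLN replicates 1 and 2, and at least 13.3 between groups. The mean per gene, which counting error alone puts at 1, was 2.23 or more for each pair, so each library was kept as a sample of its own. Nothing in the labels says that replicates came from separate animals, and p-values then measure only the spread between these libraries, which may be technical.

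Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without quality weights, other filters and thresholds, the replicate number as a block, leaving out abundant or haemoglobin genes, and leaving out each library in turn. For the lists they also included camera with an estimated correlation and the fry test. After the data were seen, edgeR fits with the coefficient of variation between replicates set to 0.1 and 0.2 were added, as was a filter on marker genes of other tissues that leaves out the reads of mLN replicate 1. Reads of genes with close copies may be split between them by the counting. This holds for Tpsb2, Mcpt4 and Cma1, Hspa1a, the class II H2 genes, Ces2c, the guanylate-binding proteins, Hbb-bt, Fth1 and the ribosomal protein genes, whose values are uncertain for this reason. Without stated strand, reads of overlapping antisense genes cannot be told apart either. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.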

Results

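Gene expression was measured in mast cells from uninvolved lymph nodes (uLN, 3 libraries) and from nodes holding tumour metastases (mLN, 3 libraries). The libraries held 17643916 to 17799420 estimated counts each. There is 1 comparison, mLN against uLN, which asks how the transcriptome of lymph-node mast cells differs where a tumour has spread to the node. The series title names lipocalin-2-positive mast cells, so Lcn2 is given first.

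Lcn2, which encodes the iron-siderophore carrier lipocalin-2, had 0 reads in all 3 uLN libraries and 45, 42 and 23 reads in mLN replicates 1, 2 and 3. The mLN level was 2.04 ± 0.627 CPM (SD, n = 3), at least 11.9-fold higher than the floor of 3 reads per library. The adjusted p was 3.13e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lcn2 (gene ID 16819) lies on chromosome 2 from 32384637 to 32387739 in GRCm38. Its reads were few, so its level within mLN is known only roughly. Of the list of lipocalin-2 and acute phase genes, 4 of 7 tested members rose and 0 fell. Slc22a17, a lipocalin-2 receptor, rose 2.74-fold from 4.38 ± 0.292 CPM in uLN (SD, n = 3). C3, the central complement component, rose 22.3-fold from 0.133 ± 0.0856 to 3.11 ± 0.152 CPM (SD, n = 3), which rests on 1, 4 and 2 uLN reads and was 33.6-fold without uLN replicate 2. Pglyrp1 rose 1.84-fold, a call that was lost without each of uLN replicates 1 and 3 and mLN replicates 1 and 3 (adjusted p from 0.0717 to 0.153 in the same edgeR test), with no expression filter (0.0624) and in DESeq2 (0.117). As a list these genes did not pass camera (adjusted p = 0.168). The list median log2 fold change of 0.88 is the same with Lcn2 set at its lower bound.

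Of 31 tested mast cell identity genes 15 fell, several of the most abundant among them, and 7 rose. Other abundant members, picked after their values were seen, did not fall. Il1rl1 and Gata2 were not called (log2 changes of 0.072 and 0.047), and Slc18a2 and Srgn rose by 0.406 and 0.187 on the log2 scale. Kit, the receptor for stem cell factor, fell from 7756 ± 191 CPM in uLN to 3139 ± 46.6 in mLN (SD, n = 3), a log2 change of -1.31 ± 0.04 (SE). Kit (gene ID 16590) lies on chromosome 5 from 75574987 to 75656722. Of the IgE receptor chains, Fcer1a and Ms4a2 fell less, by 0.59 and 0.20 on the log2 scale. The chain Fcer1g was not called (log2 change of -0.089). Cpa3, the mast cell carboxypeptidase, fell from 14730 ± 400.0 to 10920 ± 799 CPM (SD, n = 3), and Hdc, which makes histamine, fell 1.47-fold. Slc6a4, the serotonin transporter, fell 4.03-fold, Cd63 fell 2.14-fold and Tph1, the first enzyme of serotonin synthesis, fell 1.94-fold. The other 9 members of the identity list were not called, and 22 were called also when adjusted over the list alone (camera adjusted p = 0.247).

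Granule proteases moved in both directions. The chymases Cma1 and Mcpt4 rose 2.01-fold and 4.03-fold, and the tryptase Tpsb2 rose 2.06-fold from 3207 ± 140 to 6605 ± 241 CPM (SD, n = 3). The protease Cpa3 fell by 0.43 on the log2 scale. Ndst2, which the protease list also holds, is needed for heparin in granules and is not a protease. It fell 2.58-fold. In the protease list 7 of 18 members rose and 6 fell, 13 called when adjusted over the list alone (camera adjusted p = 0.559). Among all tested genes 67.4% were called, so here and in the other lists a count near that share is the background. Adjustment over a list alone gives similar counts and adds no separate evidence. In the list of connective tissue mast cell genes, which also holds Kit, Ndst2, Tpsb2 and Mcpt4, 4 of 12 rose and 6 fell, 10 when adjusted over the list alone (camera adjusted p = 0.835).

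**Figure D1:**
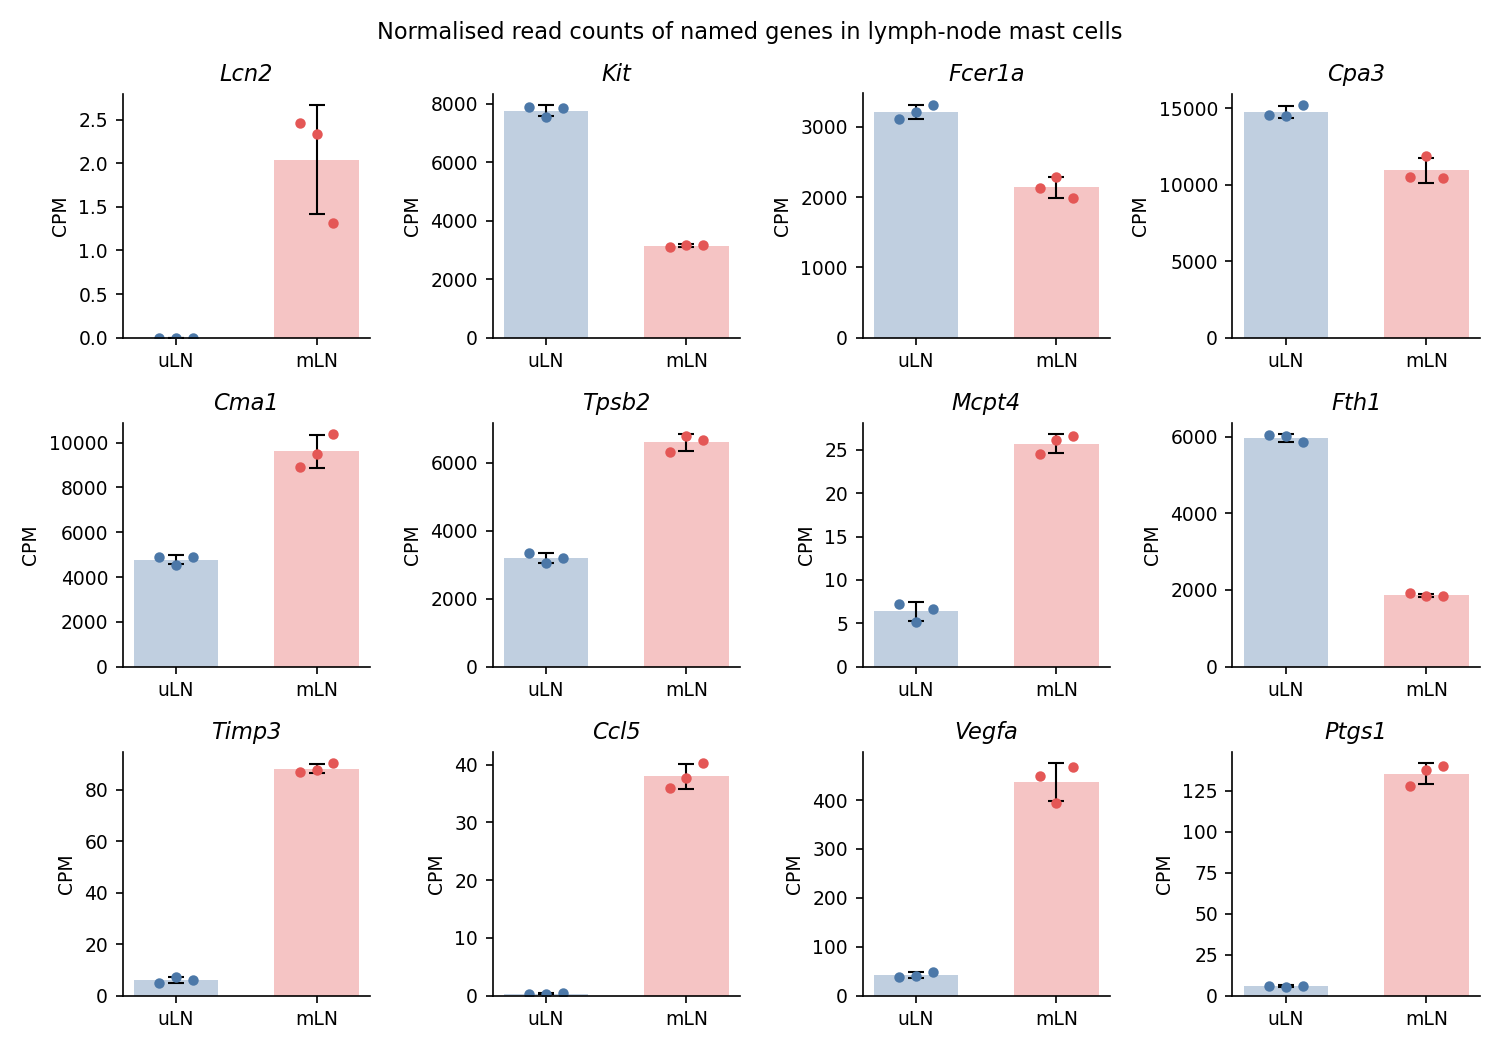
Normalised read counts in CPM (vertical axes, each from 0) of 12 named genes in uLN and mLN mast cells; bars are means, error bars SD and points the 3 libraries of each group. Kit fell from 7756 to 3139 CPM while Tpsb2 rose from 3207 to 6605 CPM, and Lcn2 had 0 reads in each uLN library.

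The largest rises were taken among genes with a mean of at least 5 CPM whose groups did not overlap, and were spread over several functions. Ces2c, a carboxylesterase, had 1 read over the uLN libraries and 371, 449 and 432 in mLN, a read ratio of 1227 with a 95% interval from 220 to 48480. Without uLN replicate 1, which held that read, Ces2c was at least 137-fold higher than the floor of 3 reads per library, and without uLN replicate 2 the ratio was 813. The chemokine Ccl5 rose 115-fold to 38.0 ± 2.14 CPM (SD, n = 3). Cyp26a1, which breaks down retinoic acid, rose 68.5-fold, the granule protease Prtn3 55.1-fold and the transcription factor Pou2f2 31.6-fold. Their uLN reads were few, and without 1 uLN library the rise was 112-fold for Cyp26a1 (replicate 1) and 49.2-fold for Pou2f2 (replicate 2). Hspa1a rose 25.8-fold, Ptgs1, which encodes cyclooxygenase-1, 23.3-fold, H2-Ab1 22.3-fold and Mpp2 22.1-fold. The largest falls among such genes were smaller in size. Styk1 fell 16.5-fold, Cd5l 9.61-fold, Ocel1 8.52-fold, the transcription factor Egr2 8.44-fold, and Dhrs4 7.58-fold. Dnase2b fell 7.57-fold, the glycine transporter Slc6a9 7.40-fold, Mmp27 7.40-fold, the transferrin receptor Tfrc 7.36-fold and the quinone reductase Nqo1 7.08-fold. Cd5l had 158, 285 and 202 reads in uLN replicates 1, 2 and 3. Gpnmb (3591, 5193 and 4417) and Cd68 (354, 527 and 430) of the macrophage list also peaked in uLN replicate 2. Cd163 of that list (197, 192 and 211) and Kit (137648, 133555 and 136454) did not. Nqo1, not on that list, peaked there too (3699, 4138 and 3844). In mLN Gpnmb fell 3.51-fold but Cd68 rose 3.62-fold. Whether Cd5l fell in mast cells or in other isolated cells was not tested.

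Over all genes, 4219 were higher and 4347 lower in mLN out of 12706 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Calls made up 67.4% of tested genes. Most calls were of modest size, as 51.8% had a fold under 1.5, and 1232 rose and 783 fell by at least 2-fold. The first principal component held 81.2% of the variance and the second 6.3%. The 2 groups did not overlap for 72.9% of tested genes, where chance gives 10%. Predicted gene models and pseudogenes made up 295 of the calls. Replicates differed little, with a coefficient of variation of 3.1% in uLN and 9.1% in mLN, and with it set to 0.2 the counts were 2145 higher and 1913 lower. Without mLN replicate 1, in which keratinocyte and fibroblast transcripts were concentrated, 4012 genes were higher and 4158 lower.

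Genes of glycolysis and the response to low oxygen rose together. Of 37 tested members 31 rose, 3 fell and 3 were not called, with a median log2 fold change of 0.92. Vegfa, the vascular growth factor, rose 10.2-fold from 42.8 ± 5.79 to 437 ± 38.6 CPM (SD, n = 3). The glycolytic enzymes Pgam1 and Aldoc rose 5.38-fold and 5.52-fold, and the collagen hydroxylase P4ha2 rose 3.58-fold. The list passed camera (adjusted p = 2.78e-07), but not with an estimated correlation (adjusted p = 0.880), and 34 members were called when adjusted over the list alone.

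Genes of antigen presentation by MHC class II rose in mLN, 9 of 11 tested members, while 2 fell. H2-Ob and H2-Oa, the chains of a peptide-loading regulator, rose 5.94-fold and 9.92-fold, and the lysosomal thiol reductase Ifi30 rose 4.66-fold. H2-Ob was the most abundant of the named members, at 160 ± 5.50 CPM in mLN against 26.9 ± 1.61 in uLN (SD, n = 3). H2-Ab1, the beta chain of a class II molecule, went from 1.23 ± 0.388 to 27.7 ± 4.27 CPM (SD, n = 3). Other members of the list stayed low in mLN. Cd74 had a mean of 4.77 CPM there, H2-Aa 1.36, Ciita 0.949 and H2-Eb1, which the filter removed, 0.576. Among markers of other antigen-presenting cells, Cd68, Adgre1 and Itgax rose 3.62-fold, 2.28-fold and 1.84-fold, while Gpnmb, Cd163, Sirpa and Lyz2 fell 3.51-fold, 2.64-fold, 1.87-fold and 1.34-fold. C1qa had 20 reads in each group, and the B cell marker Cd79a had 3 to 5 reads per uLN library and 5 to 9 per mLN library. The list median was 2.22 and it passed camera (adjusted p = 0.00786), not with an estimated correlation (adjusted p = 0.851). All 11 were called when adjusted over the list alone.

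Mitochondrial ribosomal protein genes fell by small amounts, 31 of 44 members, while 5 rose and 8 were not called. Mrpl20 fell 2.02-fold, Mrps21 1.80-fold, Mrps17 1.59-fold and Mrps23 1.54-fold. The median log2 change was -0.34 and the list passed camera (adjusted p = 0.00786), not with an estimated correlation (adjusted p = 0.880), with 37 called when adjusted over the list alone. Among nuclear genes of oxidative phosphorylation, 40 of 76 fell and 13 rose, 54 called when adjusted over the list alone. Ndufb11 fell 2.01-fold, while Ndufa6 rose 2.19-fold, Uqcrh 1.80-fold and Cox8a 1.59-fold. That list missed the camera threshold (adjusted p = 0.0514) and passed it without uLN replicate 1 (adjusted p = 0.0138), without mLN replicate 2 (adjusted p = 0.0236) and with no expression filter (adjusted p = 0.00936), but with an estimated correlation the camera adjusted p = 0.880. Of genes for mitochondrial dynamics and mitophagy, 16 of 40 rose and 13 fell, 29 called when adjusted over the list alone (camera adjusted p = 0.723). Bnip3 rose 3.73-fold and the protease Lonp1 1.53-fold, while Pink1 fell 2.35-fold and Fis1 1.62-fold.

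**Figure D2:**
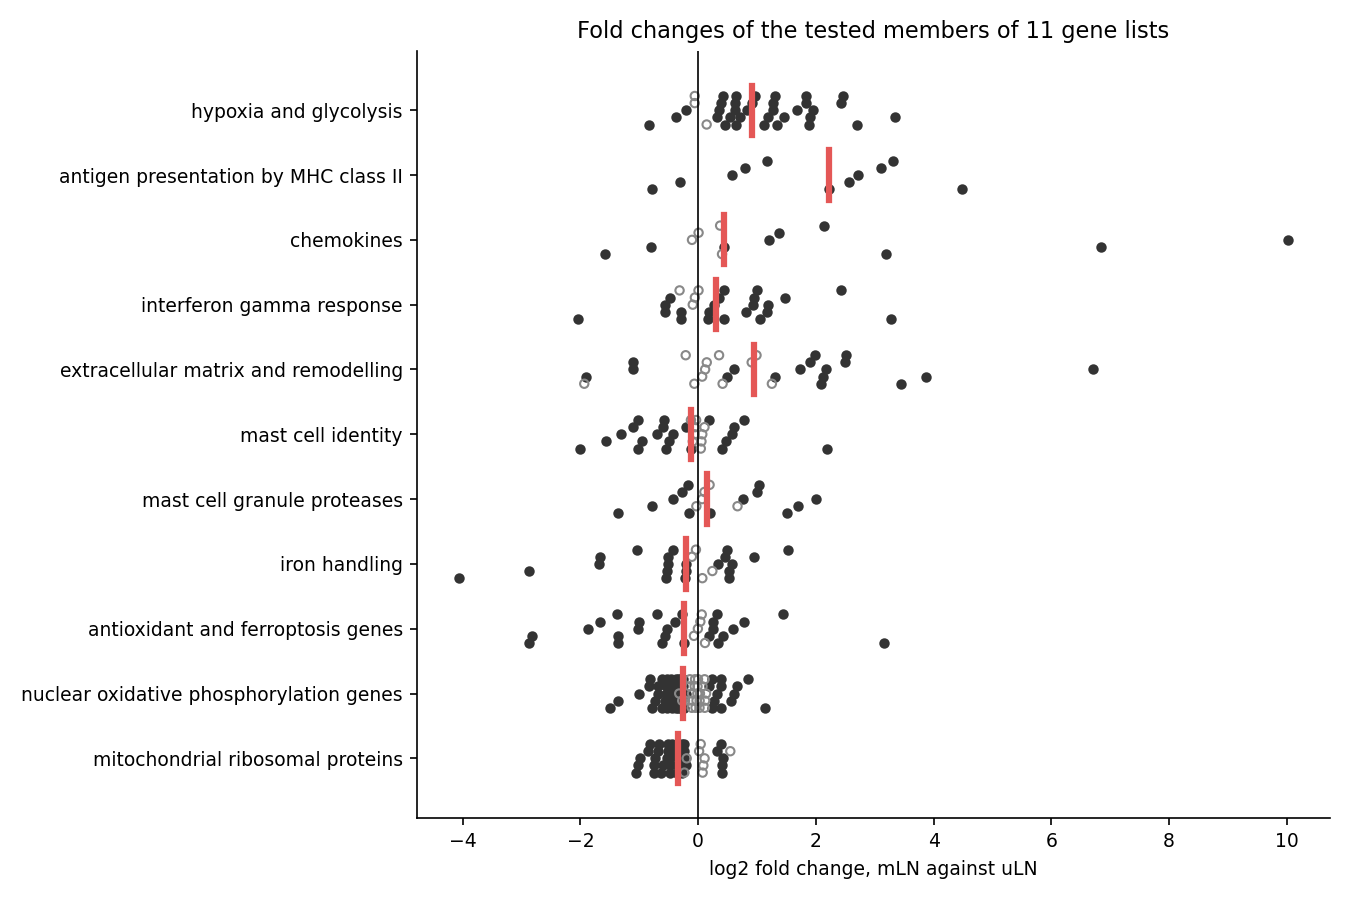
Log2 fold change of mLN against uLN (horizontal axis) for each tested member of 11 gene lists (rows); filled points were called, open points were not, and the red line is the list median. The medians were 0.92 for hypoxia and glycolysis, 2.22 for MHC class II and -0.34 for mitochondrial ribosomal proteins; the farthest chemokine point is Ccl22, a fitted value for a gene with 0 uLN reads.

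Secreted signals changed gene by gene. Among chemokines, 7 of 13 rose and 2 fell, 9 called when adjusted over the list alone (camera adjusted p = 0.247). Ccl22 had 0 reads in uLN and 97, 163 and 134 in mLN, at least 43.0-fold higher than the floor of 3 reads per library, while Ccl4 fell 2.98-fold and Ccl6 1.74-fold. The median log2 change of 0.44 is the same with Ccl22 at that bound. Of cytokines and growth factors, 9 of 22 rose and 7 fell, 16 called when adjusted over the list alone (camera adjusted p = 0.911). Il1a rose 5.21-fold, while Csf1 fell 2.75-fold and Il6 1.87-fold. Of angiogenesis genes 9 of 18 rose and 5 fell, 14 called when adjusted over the list alone (camera adjusted p = 0.553). Sema4d rose 2.05-fold and Eng 2.56-fold, and Tek fell by 1.32 on the log2 scale. In eicosanoid synthesis 5 of 18 rose and 6 fell, 11 called when adjusted over the list alone (camera adjusted p = 0.986), with a median of -0.17 against a mean of 0.33 and a test direction upward. Besides Ptgs1, Ggt5 rose 3.13-fold, and Hpgds and Alox5ap fell 2.03-fold and 1.41-fold.

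Among interferon gamma response genes 16 of 26 rose and 6 fell, 22 called when adjusted over the list alone (camera adjusted p = 0.202). The guanylate-binding proteins Gbp4 and Gbp6 rose 9.67-fold and 5.35-fold and Serpina3g 2.77-fold, whereas the immunoproteasome subunit Psmb10 fell 4.09-fold. For type I interferon 9 of 28 rose and 8 fell, 17 called when adjusted over the list alone (camera adjusted p = 0.559). Rsad2 rose 3.68-fold, Dhx58 3.81-fold, Bst2 2.29-fold and Usp18 1.89-fold. In the NF-kB and inflammatory list 15 of 34 rose and 10 fell, 25 called when adjusted over the list alone (camera adjusted p = 0.559). Bcl3 rose 8.17-fold, Nfkbia 2.99-fold and Irak2 2.29-fold. Of immediate early and heat shock genes 10 of 34 rose and 20 fell, 30 called when adjusted over the list alone (camera adjusted p = 0.553), with a median of -0.34 and a test direction downward against a mean of 0.02. Socs3 rose 5.54-fold, Ier5 4.05-fold and Jun 2.31-fold, and Hsph1 fell 2.08-fold.

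Iron and antioxidant genes fell more often than they rose. Fth1, the ferritin heavy chain, fell from 5968 ± 97.6 to 1860 ± 44.8 CPM (SD, n = 3), and Hmox1, which degrades haem, fell 3.16-fold. Blvrb rose 1.94-fold and the mitochondrial iron importer Slc25a37 rose 2.87-fold. In the iron list 8 of 25 rose and 13 fell, 21 called when adjusted over the list alone (camera adjusted p = 0.559). Of antioxidant and ferroptosis genes 10 of 31 rose and 16 fell, 26 called when adjusted over the list alone (camera adjusted p = 0.447). Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, fell 2.58-fold and 2.57-fold, and Pgd of the pentose phosphate pathway fell 3.67-fold.

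Lipid synthesis genes were mixed, with 12 of 31 rising and 14 falling, 26 called when adjusted over the list alone (camera adjusted p = 0.819). The desaturases Scd1 and Scd2 rose 11.2-fold and 2.20-fold, Acaca 2.56-fold, and Insig1 fell 3.57-fold. Of unfolded protein response genes 14 of 29 rose and 10 fell, 24 called when adjusted over the list alone (camera adjusted p = 0.559). The chaperones Hspa5 and Hsp90b1 rose 2.22-fold and 1.82-fold, while Atf4 and Ddit3 fell by 0.97 and 0.73 on the log2 scale. Of cytosolic ribosomal protein genes 38 of 78 rose and 23 fell, 62 called when adjusted over the list alone (camera adjusted p = 0.559), with a median of 0.09 and a test direction upward against a mean of -0.05. Rpl28 fell 2.85-fold, Rpl35 2.76-fold and Rpl31 2.45-fold. In the cell cycle list 15 of 48 rose and 12 fell, 27 called when adjusted over the list alone (camera adjusted p = 0.644). Cenpa rose 3.57-fold, and Mcm5, E2f8 and Pcna fell 5.05-fold, 2.07-fold and 1.86-fold.

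Transcripts of keratinocytes and fibroblasts were concentrated in mLN replicate 1, and those of melanocytes and muscle less clearly. With 20 reads asked over all 6 libraries, 12 of 12 muscle and 5 of 8 melanocytic genes peaked there. Many of them had few reads elsewhere, and better-covered ones differed little. Mylpf had 37 reads there against 20 to 31 in the other libraries, and Tyr 88 against 81 to 104. Krt5, a basal keratinocyte keratin, had 2101 reads there, 215 and 448 in mLN replicates 2 and 3, and 76 to 206 in uLN. Dcn, a fibroblast proteoglycan, had 591 reads there against 20 and 61 in the other mLN libraries. Over the epithelial, stromal, melanocytic and skeletal muscle lists, 30 of 38 genes with at least 20 reads over the other 5 libraries peaked there after scaling to library size. Their median log2 ratio to the uLN mean was 1.58 in mLN replicate 1, 0.12 in replicate 2 and 0.52 in replicate 3. With 20 reads asked over all 6 libraries, a filter that takes in genes for their reads in mLN replicate 1, 50 of 58 genes peaked there and the medians were 2.63, 0.06 and 0.47. Of epithelial and carcinoma genes 7 of 11 tested rose and 0 fell, 7 called when adjusted over the list alone (camera adjusted p = 0.553). Itga6 rose 2.76-fold at similar levels in all 3 mLN libraries, while the rises of Krt6a (5.40-fold) and Dsp (8.75-fold) came to 1.97-fold and 2.20-fold without mLN replicate 1 and were no longer called (adjusted p = 0.0596 and 0.0626 in edgeR's quasi-likelihood test). Of stromal genes 4 of 7 rose and 1 fell, 5 called when adjusted over the list alone (camera adjusted p = 0.865). Dcn (10.96-fold) and Col1a2 (5.70-fold) came to 2.04-fold and 2-fold without that library, and their calls were also lost (adjusted p = 0.0996 and 0.0576 in the same test). Without uLN replicate 3, the calls of Krt5, Krt6a, Dsp, Dcn, Col1a1 and Col1a2 were lost (adjusted p from 0.0551 to 0.0693) at folds from 2.99 to 8.63. Without uLN replicate 2, those of Dcn and Krt6a were lost (adjusted p = 0.0553 and 0.0507) at larger folds than with it (11.96 and 5.58). In limma-voom the calls of Krt5 (adjusted p = 0.0767), Krt6a, Dsp, Dcn and Col1a2 (adjusted p from 0.103 to 0.192) were lost, and with quality weights those of Dsp, Dcn and Col1a2 (adjusted p from 0.0534 to 0.12). Krt5 and Col1a1 rose 5.61-fold and 3.97-fold, and 2.07-fold and 2.08-fold without mLN replicate 1, where edgeR still called them. Pdgfrb fell 2.79-fold.

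**Figure D3:**
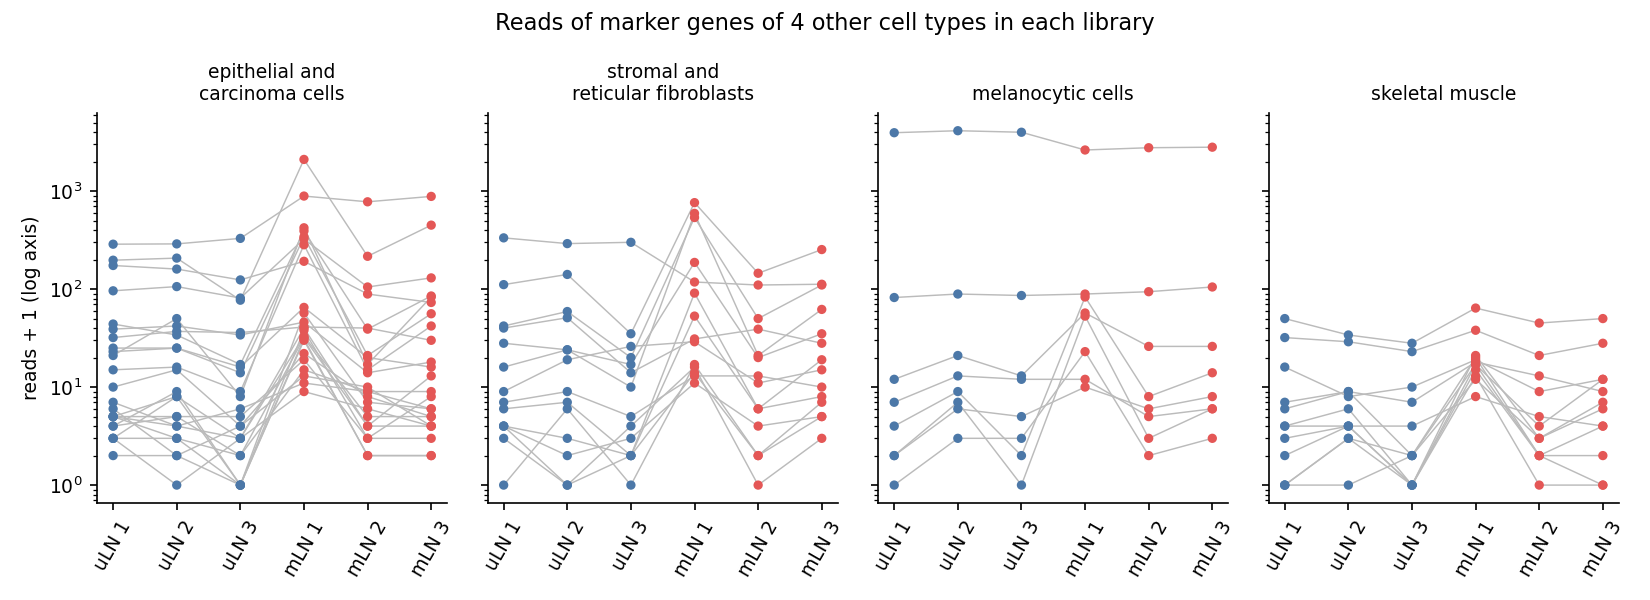
Reads plus 1 (vertical log axis) of marker genes of 4 other cell types in each of the 6 libraries (horizontal axis); points are genes with at least 20 reads in all, grey lines join the values of a gene, and uLN is blue and mLN red. After scaling to library size, 50 of these 58 genes were highest in mLN replicate 1, and 30 of the 38 that had 20 reads without that library.

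Of extracellular matrix genes 14 of 28 rose and 3 fell, 17 called when adjusted over the list alone (camera adjusted p = 0.247), and the Krt5 and Dcn values above were measured in the same libraries. Timp3 rose 14.6-fold with 1573 to 1584 reads in each mLN library, Mmp9 rose 5.61-fold and Mmp8 fell 2.16-fold. Of stem cell markers 6 of 9 rose and 2 fell, 8 called when adjusted over the list alone (camera adjusted p = 0.486). Cd24a rose 5.10-fold and Cd44 1.90-fold, similarly in all 3 mLN libraries, and Bmi1 fell 1.67-fold. Of 4 tested melanocytic genes Mitf, also a mast cell regulator, fell by 0.58 on the log2 scale and Pmel rose 2.40-fold, a call lost without mLN replicate 1 (edgeR adjusted p = 0.0767) and without uLN replicates 1 and 3 (0.0659 and 0.0646). The 3 tested muscle genes were not called, among them Atp2a1 (adjusted p = 0.124) and Mylpf (adjusted p = 0.952) by edgeR's quasi-likelihood test, and Atp2a1 passed without uLN replicate 1 (adjusted p = 0.0388).

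Marker lists of blood and immune cells did not pass camera. In the neutrophil list 3 of 8 rose and 2 fell, 5 called when adjusted over the list alone (camera adjusted p = 0.559). Besides Lcn2, Prtn3 and Mmp9, which rose, Mmp8 had 61 to 67 reads per uLN library and 25 to 34 per mLN library. Ngp, chosen after its values were seen, had 0 or 1 reads in uLN and 4, 26 and 3 in mLN, while S100a8 had 0 to 3 reads per library and S100a9 had 0 or 1. Of monocyte and macrophage genes 5 of 21 rose and 12 fell, 18 called when adjusted over the list alone (camera adjusted p = 0.559). Cd68 rose 3.62-fold and Adgre1 2.28-fold, while Gpnmb and Cd163 fell 3.51-fold and 2.64-fold. Of dendritic cell genes 3 of 8 rose and 1 fell, 4 called when adjusted over the list alone (camera adjusted p = 0.559), with Itgax up 1.84-fold, Tcf4 up 1.31-fold and Sirpa down 1.87-fold. Of B cell genes 3 of 6 rose and 1 fell, 4 called when adjusted over the list alone (camera adjusted p = 0.559). Bank1 rose 2.03-fold, and the calls of Cr2, Cxcr5 and Fcer2a were each lost without at least 1 library. Cr2 was lost without uLN replicate 1 (edgeR adjusted p = 0.0572), and Cxcr5 without uLN replicates 2 and 3 (0.0556 and 0.0630); it rose 2.77-fold, and 4.76-fold without uLN replicate 1. Fcer2a was lost without each library but mLN replicate 1 (edgeR adjusted p from 0.0512 to 0.103), with no expression filter (0.0627) and in DESeq2 (0.164). Of T cell genes 1 of 7 rose and 3 fell, 4 called when adjusted over the list alone (camera adjusted p = 0.559). Lat, which mast cells also use, fell 2.08-fold, Cd4 3.22-fold and Cd28 3.90-fold, and Il7r rose 1.45-fold.

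In the basophil and eosinophil list 5 of 10 rose and 3 fell, 9 called when adjusted over the list alone (camera adjusted p = 0.559). Prss34 rose 2.86-fold, Ccr3 2.30-fold and Cd200r3 1.53-fold, and Il5ra fell 3.12-fold. Of endothelial genes 2 of 7 rose and 3 fell, 5 called when adjusted over the list alone (camera adjusted p = 0.845), with a median of 0.00 and a test direction downward against a mean of 0.19. Vwf fell 2.10-fold, and Flt4 went from 0 to 2 reads per uLN library to 10 to 20 per mLN library (a read ratio of 14.0 with a 95% interval from 4.49 to 70.8, and 28.2 without uLN replicate 3). Of megakaryocyte genes 4 of 9 rose and 4 fell, 8 called when adjusted over the list alone (camera adjusted p = 0.911), with a median of -0.23 and a test direction downward against a mean of 0.23. Itga2b, also abundant in mast cells, fell 1.79-fold, Pf4 rose 9.18-fold and Nrgn 1.46-fold. Of erythroid genes 3 of 6 rose and 1 fell, 4 called when adjusted over the list alone (camera adjusted p = 0.619). Car2 rose 2.48-fold, Epor 4.46-fold and Hbb-bt 6.45-fold (14.0-fold without uLN replicate 3). Lists with under 5 tested members had no list test. Of 2 plasma cell genes both rose, Xbp1 1.42-fold and Sdc1 2.70-fold. Sdc1 was not called without uLN replicates 1 and 3 or mLN replicate 1 (edgeR adjusted p from 0.0696 to 0.0927), and its fold was 1.69 without mLN replicate 1. Of 2 cytotoxic cell genes Ccl5 rose and Eomes was not called (edgeR adjusted p = 0.106), though it passed without mLN replicate 3 (adjusted p = 0.000118) and in limma-voom with quality weights (adjusted p = 0.00166). Of 3 adipocyte genes Lipe rose 1.16-fold and Fabp4 and Pparg fell 3.14-fold and 2.73-fold, Pparg not without uLN replicate 2 or mLN replicate 2 (edgeR adjusted p = 0.0552 and 0.0575) or in DESeq2 (adjusted p = 0.0643), and 4.32-fold without mLN replicate 1.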

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

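The counts with the coefficient of variation set by hand and the filter without mLN replicate 1 were chosen after the data were seen, and the other alternatives before. Higher and lower counts stayed within 1.5 times 4219 and 4347 under the alternatives run, apart from those named next, and 0 of the calls shared with an alternative changed direction. The exceptions were the demand for a log2 fold change of at least 1, which left 1232 higher and 783 lower, as it removes smaller changes by construction, and a coefficient of variation of 0.2, which left 2145 and 1913. Leaving out single libraries gave 3843 to 4403 higher and 4017 to 4492 lower. The stricter p and fold thresholds reused the main fit, so no direction could change under them. Other scaling factors moved no log2 fold change by more than 0.041. Each scaling put the median log2 change of all tested genes between -0.006 and 0.021. A shift shared by most genes could therefore not be seen, and the near-even split of calls depends on this scaling. Deviations from the group mean correlated at 0.02, -0.15 and -0.01 between same-numbered libraries. No mLN library correlated best with the uLN library of its own number. With 3 libraries per group that differ little, these values cannot decide whether same-numbered libraries share an animal or a batch. With the replicate number as a block 4122 genes were higher and 4263 lower, and Pglyrp1 and Fcer2a were no longer called. Of the gene lists, 3 were called by camera, 0 with an estimated correlation and 23 by fry, which does not compare a list with other genes; the cause was not tested. Of 2618 values for 156 named genes under alternatives, 2568 kept their call, 47 lost it, 3 gained it and 0 reversed. Lcn2 was not tested with a minimum of 5 CPM, which its level does not reach. Leaving out mitochondrial-genome transcripts was not run, as none are in the table. At this depth genes under 0.172 CPM in a library, 3 reads, could not be told from 0.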

Other observations

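Genes in this paragraph were chosen after their values were seen. Txnip, an inhibitor of glucose uptake that is induced by glucose-derived metabolites, rose from 1893 ± 45.7 to 8434 ± 1700 CPM (SD, n = 3). Its relative Arrdc4, under the same control, rose 13.0-fold from 3.90 ± 0.761 to 50.7 ± 7.03 CPM (SD, n = 3). Cyp26b1, like Cyp26a1 a retinoic acid hydroxylase, rose 9.50-fold. Klf10 and Ltbp4 rose 15.7-fold and 15.4-fold. Egr1, an immediate early transcription factor, fell from 2925 ± 461 to 816 ± 327 CPM (SD, n = 3), and Csf2rb2 and Csf2rb, near-identical chains of the interleukin-3 receptor whose counts are uncertain for that reason, fell 3.01-fold and 1.98-fold. The adjusted p of each of these genes was 7.67e-05 or lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

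The tests of TGF-beta induced genes and of epidermis and hair genes were set before the values of those genes were looked at, the latter after the pattern it bears on was seen, and the other tests in this part were chosen after the results were seen. The real split of the 6 libraries called 8566 genes and the highest of the other splits called 0 by edgeR, with 31 to 95 genes at an unadjusted p under 0.05 and at most 1 called by limma-voom. The real split was the only 1 of the 10 splits with as many, and 10 splits are too few for a share under 0.05.

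Lcn2 reads in mLN may come from other cells. Neutrophils bring S100a8 and S100a9 in large amounts, but these had 2 reads over the mLN libraries against 110 for Lcn2, a ratio of 0.0182 (95% interval 0.00218 to 0.0673), which argues against neutrophils as the whole source. Ngp, another neutrophil granule gene, had 33 reads in mLN, of which 26 were in replicate 2, where Lcn2 had 42. The material of mLN replicate 1 is argued against as the source too, as Lcn2 was 1.05 times as high in mLN replicate 1 as in replicate 2 (95% interval 0.678 to 1.65), where Krt5 was 9.63 times as high (8.36 to 11.1). Lcn2 from the mast cells themselves stays open as a hypothesis, as do other cell types not tested.

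Keratinocyte and fibroblast transcripts peaked in mLN replicate 1, and melanocyte and muscle transcripts did so less clearly. A change of like size in all mLN mast cells was argued against by mLN replicate 2. Its median log2 ratio to uLN was 0.06 over 58 marker genes (interquartile range -0.52 to 0.48). Over the 38 that had 20 reads without replicate 1 it was 0.12 (-0.44 to 0.55), against 1.58 in replicate 1. In replicate 3 the medians were 0.47 and 0.52, and Krt5 and Col1a1 were still called without replicate 1. A smaller rise in some mLN libraries thus stays open. Skin-type tissue or carried-over reads were tested on epidermis and hair genes outside the fixed lists, of which 6 of 8 with at least 10 reads were higher in mLN replicate 1 than in replicate 2 (2-sided exact binomial p = 0.289), too few to decide. Asprv1 and Calml3 had 449 and 416 reads in replicate 1 against 64 and 53 in replicate 2, but Tgm1 had 80 against 110, and Krt1, Krt10 and Lor, abundant in epidermis, had 0 or 1 reads in both. Of inner organ genes with at least 10 reads, 3 of 5 were higher in replicate 1 than in replicate 2. Among them Ttr had 88 reads in replicate 1 against 0 and 11 in mLN replicates 2 and 3. Tumour cells of the mLN nodes were not tested as a source, and the tumour type is not given in the sources used here. The source of the keratinocyte, fibroblast, melanocyte and muscle transcripts stays open.

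The rise of H2-Ob and H2-Oa was weighed against B cells, dendritic cells or macrophages among the isolated cells. Cd74, the most abundant class II transcript of such cells, rose by 71.7 reads per library against 2358 for H2-Ob and 587 for H2-Oa, ratios of 0.0304 and 0.122 where such cells would give 1 or more, which argues against them for these genes. H2-Ab1, not part of that test, rose by 469 reads per library. For the smaller rise of Cd74, H2-Aa and H2-Eb1 they cannot be told apart from a change in mast cells. The read ratio of mLN to uLN was 1.66 for Cd79a (95% interval 0.799 to 3.58) and 0.980 for C1qa (0.50 to 1.92). Both were below the 6.60 of Cd74 (4.68 to 9.54), and the ratio was 0.744 for Lyz2. The C1qa and Lyz2 ratios go against C1qa-expressing macrophages. B cells stay open, as the Cd79a interval allows a rise. Of the B cell list, Bank1 rose 2.03-fold, Cxcr5 2.77-fold and Fcer2a 1.75-fold, while Cr2 fell 2.11-fold. The calls of Cxcr5, Fcer2a and Cr2 were each lost without at least 1 library. Cd68, Adgre1 and Itgax rose 3.62-fold, 2.28-fold and 1.84-fold, which keeps dendritic cells and other macrophages open, and how much Cd74 a few B cells bring per Cd79a read is not in these data.

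A hypothesis is that NRF2, a transcription factor for antioxidant genes, may be less active in mLN, as its targets Nqo1, Gclm, Gclc, Pgd, Hmox1 and Fth1 fell. Whether these falls took place in mast cells or in other isolated cells was not tested. Of 25 other tested targets, 16 fell and 7 rose, with a median log2 change of -0.39. The camera p was 0.0354, but 0.0708 adjusted over the 2 hypothesis lists and 0.137 with an estimated correlation, so the result fails the correction. The demand for adjustment was set after that p was seen, and 9 of the 25 genes belong to the antioxidant list whose counts were already known. Among the targets Srxn1 fell 2.61-fold and G6pdx 2.01-fold, while Ephx1 rose 3.18-fold. Gsta4, also counted as rising, had 334 reads in mLN replicate 1 against 24 and 48 in the other mLN libraries, and the camera p was 0.0401 without that library. The hypothesis stays open.

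A second hypothesis, a response to TGF-beta, came from the rise of Klf10, Timp3 and Ltbp4. Of 20 other tested TGF-beta induced genes 11 rose and 6 fell, with a median log2 change of 0.37, and the camera p of 0.394 did not pass, nor did 0.535 with an estimated correlation. Ltbp3 rose 7.33-fold, while Itgae fell 2.15-fold and Tgfb1i1 3.95-fold. Tgfbi, also counted as rising, had 133 reads in mLN replicate 1 against 21 and 36 in the other mLN libraries, and the camera p was 0.309 without that library. The test does not decide whether such a response may be present.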
